A study of Mus musculus with 6 samples.

How the data were processed

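A set of 6 libraries of polyadenylated RNA from MII eggs of 8-week-old mice was used, 2 for each of 3 groups: H3.3, K27R and R26K. Groups and replicate numbers were taken from the sample titles. Per the labels, cDNA was made with the SMARTer Ultra Low RNA kit, which primes on poly(A) tails, and libraries with the Nextera kit, which does not mark the strand; they were read on a HiSeq 2000 as single 50-base reads. Per the submitters' processing notes, cutadapt 1.9.1, TopHat2 2.1.0, SAMtools 1.3 and featureCounts were used with the mouse build mm10; the annotation, the treatment of reads that map to several places and the strand setting were not given in the sources used here. The deposited table holds whole-number read counts per gene, without normalization, for 24062 gene symbols in 6 columns, each of which matched 1 sample; 0 columns were left out and every gene had a name. Mitochondrially encoded genes were not analysed here, because none of the 15 in that list was found in the table. Total counts ranged from 10803477 to 39603440 per library, so that 3 counts stand for 0.285 CPM in the smallest library and 0.0815 CPM in the largest.

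From the deposited counts, levels were computed as CPM, counts scaled to the library total, after scaling by the trimmed mean of M values (TMM). Genes were kept by edgeR's filterByExpr with the group (10667 genes, holding at least 99.8% of the counts of each library). Differences were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) in 1 fit of all 6 libraries with 3 group means, so that the groups shared 1 estimate of spread with 3 residual degrees of freedom; tests were two-sided and adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. The common dispersion was 1.63. Standard errors are the log2 fold change divided by the square root of the F statistic. The labels call the libraries biological replicates but do not say whether they came from separate females, so p-values measure the spread between these libraries. For a gene without counts in 1 group a lower bound was computed against 3 counts per library; for 1 to 3 counts the ratio of counts is given with its 95% interval. Gene lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01) and, as alternatives, with an estimated correlation and with fry, adjusted over the 23 lists with at least 5 tested genes. Calls were also counted adjusted over the list alone.

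The 24 lists were: oocyte-specific genes, maternal-effect genes, maternal mRNA storage and decay, meiotic spindle and cell cycle, Polycomb complexes and H3K27 demethylases, H3K27 acetylation enzymes, arginine methyltransferases and deiminases, H3.3 genes with chaperones and histone supply, DNA methylation machinery, H3K27me3-marked developmental regulators, genes imprinted by maternal H3K27me3, genes imprinted by DNA methylation, 2-cell and zygotic activation genes, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, proteasome, p53 response, DNA repair, heat shock and unfolded protein response, retrotransposon silencing, cumulus and granulosa markers, markers of other oviduct cells, and immediate early genes. Genes are named by a rule: H3f3a and H3f3b always; among called genes with a mean of at least 10 CPM, groups that do not overlap and a symbol that is not a clone or predicted name, the 10 with the largest change in each direction (5 for K27R against R26K); up to 3 called members of each list, or the member with the smallest p where none was called; and, for a comparison with fewer than 3 calls, the 10 genes with the smallest p. Genes outside the rule are said to have been chosen after their values were seen. The rule named 47 genes for R26K against H3.3, 34 for K27R against H3.3 and 35 for K27R against R26K, and 1 of these genes is not reported here. The others not printed did not pass the test. The tests of genes, lists and correlated effects, the lists, this rule and the alternatives, except those said to be added, were fixed before the data were examined. The tests of explanations in the closing parts, including those on the polyadenylation element and on pseudogenes, were not part of that plan.

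Alternatives were DESeq2 1.42.0, relative log (RLE) and upper-quartile scaling, no filter, a filter of 10 CPM on the mean, a fit of only the groups compared, the replicate number as a block, robust estimation of the spread, and each library left out in turn; a filter of 50 CPM, thinning to the smallest library and a correction for GC content and length were added after the data were seen. For the correction, each library's deviation from the gene mean was fitted with loess on GC content and log length over genes with a mean of at least 50 CPM, and the fit was added to the offsets. The steps were tested on counts simulated at the real depths, in 5 simulations per changed group. Apart from the changes made, a gene had the same mean and dispersion, estimated from the data, in every library. The rates thus hold for groups of equal spread, while the real replicates correlated at 0.577 in H3.3 and 0.943 in R26K. In each, 200 genes were changed and a list of 30 further genes was shifted 4-fold. In the comparison of R26K with H3.3 (9826 genes tested on average), edgeR recovered 11.1% of genes changed 4-fold, 39.2% of those changed 16-fold and 62.2% of those changed 64-fold. Its false calls were 9.31% of false calls and recovered genes together, with calls in the list of 30 left out. DESeq2 made 295 false calls per simulation in that comparison. Where K27R was left unchanged, edgeR made 1.2 and DESeq2 226 false calls per simulation between K27R and H3.3. Camera called a list shifted 4-fold in 5 of 5 simulations of R26K against H3.3, and 0 of 5 with an estimated correlation.

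Positions are from GENCODE M21, which is on the build mm10; 98.6% of the symbols matched it. Near-identical copies were found with blastn 2.17.0 (at least 95% identity over 200 bases). For the test on ribosomal protein genes alone, pseudogenes were counted at 90% identity or more over at least 150 bases. A cytoplasmic polyadenylation element was searched in the last 100 bases of the annotated 3' UTR. Figures were drawn with matplotlib 3.10.9.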

Results

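Messenger RNA was profiled in mouse metaphase II (MII) eggs, the ovulated and unfertilized stage, that expressed 1 of 3 tagged forms of the replacement histone H3.3. The forms were unmutated H3.3 joined to eGFP, H3.3 with lysine 27 replaced by arginine joined to mCherry (here K27R), and H3.3 with arginine 26 replaced by lysine joined to eCFP (here R26K). Each form thus had its own tag, and tag and substitution cannot be told apart in any comparison. The females carried the multicolour transgene HISRainbow and the oocyte recombinase Figla-iCre, and the colour of each egg was read under a confocal microscope. Each form had 2 libraries, which the labels call biological replicates. The number of eggs and females behind a library was not given in the sources used here. Gene counts totalled 12748821 and 11452906 in the H3.3 libraries, 11557291 and 10803477 in the K27R libraries, and 39603440 and 33786225 in the R26K libraries. The table held 24062 genes, of which 10667 passed the expression filter and were tested.

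The libraries differed in how many genes had counts. The R26K libraries had at least 1 count for 12135 and 12112 genes and K27R replicate 1 for 10715. The numbers were 7590 in H3.3 replicate 1, 7392 in H3.3 replicate 2 and 7405 in K27R replicate 2. After random thinning of every library to 10803477 counts they were 11829 and 11856 in R26K, 10692 and 7405 in K27R, and 7504 and 7352 in H3.3. Of the genes that averaged 10 to 20 CPM (counts scaled to library size) in the other libraries, 472 of 1464 had no count in H3.3 replicate 1 and 503 of 1415 in H3.3 replicate 2. In K27R the numbers were 81 of 1475 in replicate 1 and 487 of 1437 in replicate 2, and in R26K 26 of 1426 and 21 of 1452, so they also differed within a group. Replicates correlated across genes at 0.577 in H3.3, 0.726 in K27R and 0.943 in R26K (Pearson r of log2 CPM over 6135 genes, which are not independent replicates). Across groups, H3.3 replicate 1 correlated at 0.744 with K27R replicate 1 and at 0.631 with K27R replicate 2, and H3.3 replicate 2 at 0.681 with K27R replicate 1, so the H3.3 libraries agreed less with each other than with these. K27R replicate 1 correlated with R26K replicate 1 at 0.725. Of 36 markers of cumulus and granulosa cells, which surround the egg, 8 and 16 had a count in the H3.3 libraries, 22 and 6 in K27R, and 24 and 20 in R26K. Serpine2, the most abundant, was at 941 and 1241 CPM in H3.3, 1655 and 1394 in K27R, and 1914 and 1814 in R26K. Other markers were chosen after their values were seen. Tnfaip6, a gene of cumulus expansion, was at 186 CPM in H3.3 replicate 2, 86.9 in K27R replicate 1 and 29.4 in R26K replicate 1, lower in R26K replicate 2, and without a count in H3.3 replicate 1 or K27R replicate 2. Ptgs2 was at 23.8 and 31.4 CPM in H3.3, had no count in K27R, and was at 5.02 CPM in R26K replicate 1 with no count in R26K replicate 2. Cyp11a1 had no count in H3.3, and was at 38.3 and 0.0950 CPM in K27R and 9.23 and 15.7 CPM in R26K. Inha and Akr1c18 had no count in H3.3 replicate 1 or K27R replicate 2. Of 35 markers of blood, immune, stromal and epithelial cells, 7 and 5 had a count in H3.3, 9 and 5 in K27R, and 9 and 9 in R26K. Pecam1 was at 15.4 to 156 CPM in all libraries. H2-Aa was above 32 CPM in H3.3 replicate 1 and K27R replicate 2, and at most 1.88 CPM elsewhere. C1qb was at 7.17 and 17.1 CPM in K27R, and Krt8 and Krt18 at 11.7 and 10.5 CPM in R26K replicate 1. Cd68 had counts in 4 libraries, and the 6 haemoglobin genes had none.

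**Figure D1:**
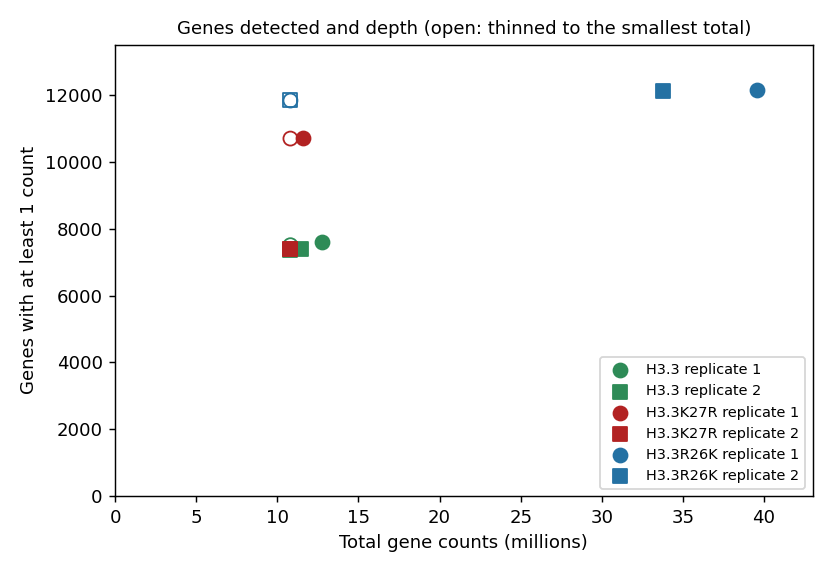
Number of genes with at least 1 count (vertical axis) against total gene counts (horizontal axis), 1 filled symbol per library and an open symbol for the same library thinned to 10803477 counts. After thinning the R26K libraries have 11829 and 11856 genes, while both H3.3 libraries and K27R replicate 2 have 7352 to 7504.

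The 2 genes that encode H3.3 were measured first. H3f3b (chromosome 11, 116021912 to 116027962 on mm10) was at 3721 and 3901 CPM in H3.3, 3157 and 4477 in K27R, and 2830 and 1910.0 in R26K. H3f3a (chromosome 1, 180800832 to 180813943) was far lower, at 63.9 and 104.8 CPM in H3.3, 80.0 and 67.6 in K27R, and 35.7 and 38.2 in R26K. Neither passed the test in any comparison. Against H3.3, the log2 fold change of H3f3b was 0.0021 ± 0.28 (SE) in K27R and -0.69 ± 0.28 in R26K, with edgeR adjusted p of 1 and 0.230. Its sign in K27R changed with the scaling. GENCODE lists 16 near-identical pseudogenes of H3f3a and 2 of H3f3b. Reads of the transgene cannot be told from those of the endogenous genes here, so these counts do not check which form an egg expressed.

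The first comparison asked which transcripts differed between eggs with R26K and eggs with unmutated H3.3. Among abundant egg transcripts, Zar1, a maternal mRNA-binding protein, rose from 194 and 270 CPM in H3.3 to 4316 and 4089 CPM in R26K, a log2 fold change of 4.18 ± 0.28 (SE, 2 libraries per group, edgeR adjusted p = 0.0113). Zbed3, a member of the subcortical maternal complex, rose from 1452 and 1339 CPM to 14569 and 13679 CPM (3.34 ± 0.25). In the other direction, Paip1, a translation factor that binds the poly(A)-binding protein, fell from 6263 and 6641 CPM to 202 and 128 CPM (-5.29 ± 0.33). Arid5b, a DNA-binding regulator, fell from 225 and 312 CPM to 2.69 and 3.18 CPM (-6.51 ± 0.46). With a correction for GC content and length, chosen after the data were seen, Zar1 (2.02) and Zbed3 (2.19) no longer passed (edgeR adjusted p = 0.0585 for both). Paip1 and Arid5b kept their calls under it. On mm10 these genes lie on chromosome 5 from 72576806 to 72581254 (Zar1), chromosome 13 from 95323612 to 95337841 (Zbed3) and from 119428601 to 119458218 (Paip1), and chromosome 10 from 68092520 to 68278740 (Arid5b). In all, 43 of 10667 genes were higher and 23 lower in R26K (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), by at least 3.09-fold. Both R26K libraries lay outside the range of the other 4 in all 66, and in 35.5% of all tested genes (2875 above and 911 below). Interchangeable libraries would give 13.3%. However, the libraries differed in the number of genes detected, and 2210 tested genes had no count in either H3.3 library.

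Other genes that rose in R26K were Mybl2, a cell cycle transcription factor (5.46 ± 0.57), Bcl7c, a subunit of the BAF remodelling complex (5.37 ± 0.70), and Zfp212 (4.92 ± 0.62). Fam69b rose from 0.153 and 0.510 CPM to 190.3 and 117 CPM. Stx6, Fam50a and Mad2l2 had no count in either H3.3 library, where 3 counts per library would be 0.230 and 0.255 CPM. In R26K they were 804-fold, 483-fold and 321-fold above this floor. Cxxc1, a CpG-binding subunit of histone H3 lysine 4 methyltransferase complexes, had 1 count in H3.3 and 7538 in R26K, a ratio of 2677 with a 95% counting interval from 480.4 to 105759. That interval and the floors cover counting error only, since reads of amplified cDNA are not independent molecules. Stx6, Fam50a, Mad2l2 and Cxxc1 were also counted in both K27R libraries, at 18.9 to 67.2 CPM. Genes that fell included Uvssa, of transcription-coupled repair (-4.45 ± 0.52), Klhl9 (-4.18 ± 0.46), Wtap, of the RNA m6A methyltransferase (-3.85 ± 0.32), Sept2 (-3.85 ± 0.44) and Arl14ep (-3.76 ± 0.42). Tmbim6 (-3.58 ± 0.38), Camk2g, a calmodulin-dependent kinase of egg activation (-3.57 ± 0.42), and Khsrp, an mRNA decay factor (-3.56 ± 0.46), also fell. Reads of Bcl7c could include those of the overlapping Mir762, and Klhl9 has a near-identical copy, Gm26566. Near-identical pseudogenes exist for Wtap (2), Zar1, Mybl2, Bcl7c and Khsrp (1 each), so the levels of these genes are less certain.

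**Figure D2:**
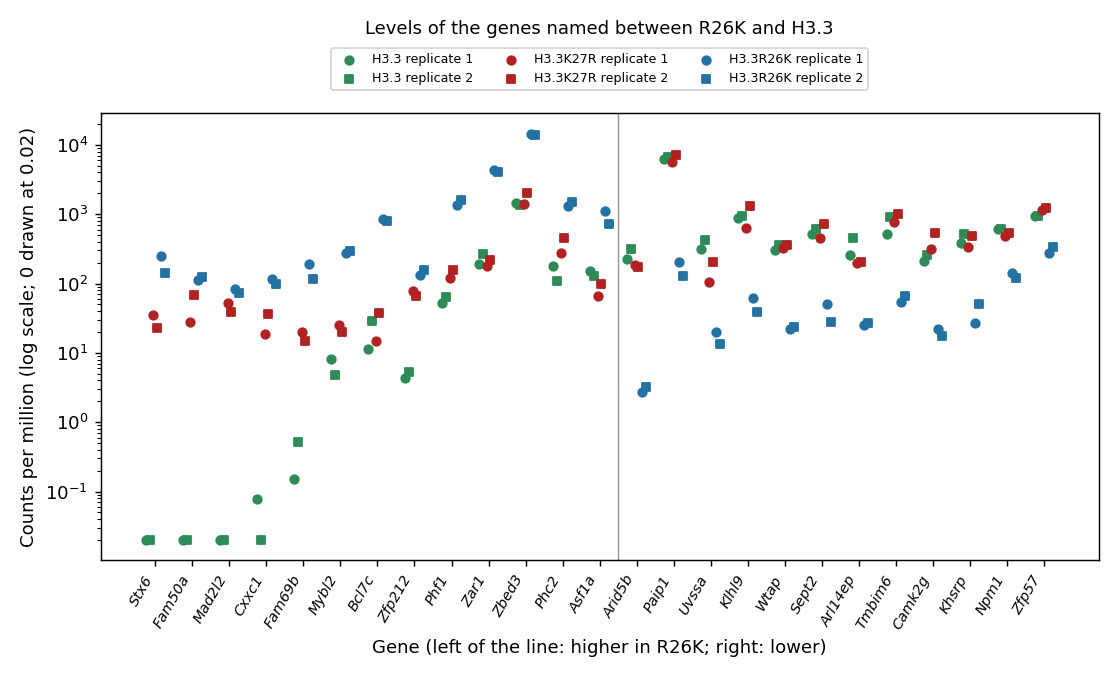
Level in CPM (log axis, values of 0 drawn at 0.02) in each of the 6 libraries for genes that passed the test between R26K and H3.3, those higher in R26K on the left and those lower on the right. For each gene both R26K libraries lie outside the other 4; Zbed3 reaches 14569 CPM and Arid5b falls to 2.69 CPM.

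The called genes were then set against the 23 lists. Of the maternal-effect list, 2 of 37 tested members rose (Zar1 and Zbed3), 1 fell and 34 did not pass. The member that fell was Zfp57, a zinc finger protein that maintains imprints, from 933 and 954 CPM to 280 and 332 CPM (-1.63 ± 0.22, edgeR adjusted p = 0.0486). Adjusted over the list alone, 4 rose and 3 fell. Of the Polycomb and H3K27 demethylase list, 2 of 35 rose and none fell, and 4 rose adjusted over the list alone. Phf1 (chromosome 17, 26933052 to 26937908), an accessory subunit of Polycomb repressive complex 2, went from 52.6 and 63.8 CPM to 1370 and 1607 CPM (4.68 ± 0.31, adjusted p = 0.0113). Phc2, of Polycomb repressive complex 1, went from 179.8 and 107.7 CPM to 1329 and 1510 CPM (adjusted p = 0.0352). After a correction for GC content and length, chosen after the data were seen, neither passed, with log2 fold changes of 2.14 for Phf1 (adjusted p = 0.0777) and 0.72 for Phc2 (0.345). Of the list of H3.3 genes, chaperones and histone supply, 1 of 36 rose, the H3-H4 chaperone Asf1a (2.69 ± 0.36, adjusted p = 0.0448), and 1 fell, nucleophosmin Npm1 (-2.22 ± 0.25, adjusted p = 0.0329). Adjusted over the list alone the counts were the same. Zfp57 was also the 1 member of 28 called in the DNA methylation list, where 1 rose and 2 fell adjusted over the list alone. The other 19 lists had no member that passed over all genes. Exons of Phf1 overlap those of Cuta and exons of Asf1a those of Mcm9, and the strand setting of the counting was not given. Npm1 has 4 near-identical pseudogenes.

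As sets, 3 lists stood lower than the other tested genes in R26K by camera with a preset correlation, and none of these calls held with an estimated correlation (adjusted p = 0.826 for each). The cytosolic ribosomal proteins had 47 of 52 members below 0, with a median log2 fold change of -1.64 (adjusted p = 7.0e-10), and no single member passed. Rpl13a, with the smallest p, had 63.2 and 106.3 CPM in H3.3 and 22.9 and 18.2 CPM in R26K. It overlaps Mir5121 and Snord33 and has 2 near-identical pseudogenes. The oocyte-specific genes had 18 of 27 members below 0 (median -0.27, mean -0.02, adjusted p = 0.00081). Among them Oosp2 was at 809 and 1027 CPM in H3.3 and 315 and 392 CPM in R26K (edgeR adjusted p = 0.0834). The list of meiotic spindle, kinetochore and cell cycle genes was called downward (adjusted p = 0.0271) although 35 of 70 members lay on each side of 0, with a median of 0.02 and a mean of 0.35. Camera compares a list with all tested genes, whose median was 0.66, while that of the 2854 genes with a mean of at least 50 CPM, a bound chosen after the data were seen, was 0.02. Of the tested genes 2210 had no count in either H3.3 library. The spindle call is thus relative to a background that includes these genes, and the median of the list was close to that of the abundant genes. The list's median became negative with relative log and upper-quartile scaling. Without H3.3 replicate 2 the ribosomal median was -0.92 and the oocyte list did not pass (adjusted p = 0.0758). The spindle list did not pass without H3.3 replicate 1 (0.217) or H3.3 replicate 2 (0.0758).

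The other 20 lists did not pass camera in R26K. Adjusted p was 0.0646 for the proteasome, 0.192 for oxidative phosphorylation, 0.300 for arginine methyltransferases and deiminases, and 0.514 for H3K27me3-marked regulators and for genes imprinted by maternal H3K27me3. It was 0.576 for maternal-effect genes, mRNA storage and decay, H3K27 acetylation, retrotransposon silencing and immediate early genes. It was 0.675 for the Polycomb, H3.3 and chaperone, DNA methylation, imprinted and heat shock lists. The values were 0.726 for markers of other oviduct cells, 0.755 for zygotic activation genes, 0.786 for DNA repair and for cumulus markers, and 0.799 for the p53 response. By fry, no list moved one way (lowest adjusted p = 0.0728), while 18 lists held genes that differed in either direction. The latter test does not compare a list with other genes. Of all tested genes 21.7% had an unadjusted edgeR p under 0.05, so it shows no change particular to these lists.

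The calls between R26K and H3.3 depended on the setting: DESeq2 called 1207 higher and 421 lower, upper-quartile scaling gave 31 and 27, a fit of only these 4 libraries gave 0 and 0, and leaving out a library gave 1 and 0 (K27R replicate 1 or K27R replicate 2), 147 and 30 (H3.3 replicate 1), 15 and 5 (H3.3 replicate 2), 137 and 56 (R26K replicate 1) or 140 and 46 (R26K replicate 2). The folds of the 66 genes stayed while the calls changed: all kept their direction, and their median absolute log2 fold change was 3.39 with all libraries and in the fit of 4, 3.39 without K27R replicate 1 and 3.38 without K27R replicate 2. This was all but fixed in advance. K27R libraries enter these folds only through the scaling, and both R26K libraries lay outside the other 4 in each of the 66 genes. It shows where the calls were lost, and not that the folds are stable. An unadjusted p under 0.05 was reached by 2317 genes with all libraries and by 3513 in the fit of 4. The correction of each library for GC content and length gave 6 higher and 17 lower and kept 17 of the 66 calls. Of the 7 called list members only Asf1a (log2 fold change 3.58) kept its call. Besides Phf1 and Phc2, calls ended for Zar1 (2.02, edgeR adjusted p = 0.0585), Zbed3 (2.19, 0.0585), Zfp57 (-1.82, 0.0635) and Npm1 (-1.70, 0.0646). Of the other genes named above, Arid5b (-6.93), Paip1 (-4.63), Stx6, Wtap, Tmbim6 and Khsrp kept theirs. Mybl2 (3.70, 0.0630), Bcl7c (3.56, 0.0968), Zfp212, Fam50a, Mad2l2, Cxxc1, Fam69b, Uvssa, Klhl9, Sept2, Arl14ep and Camk2g did not.

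**Figure D3:**
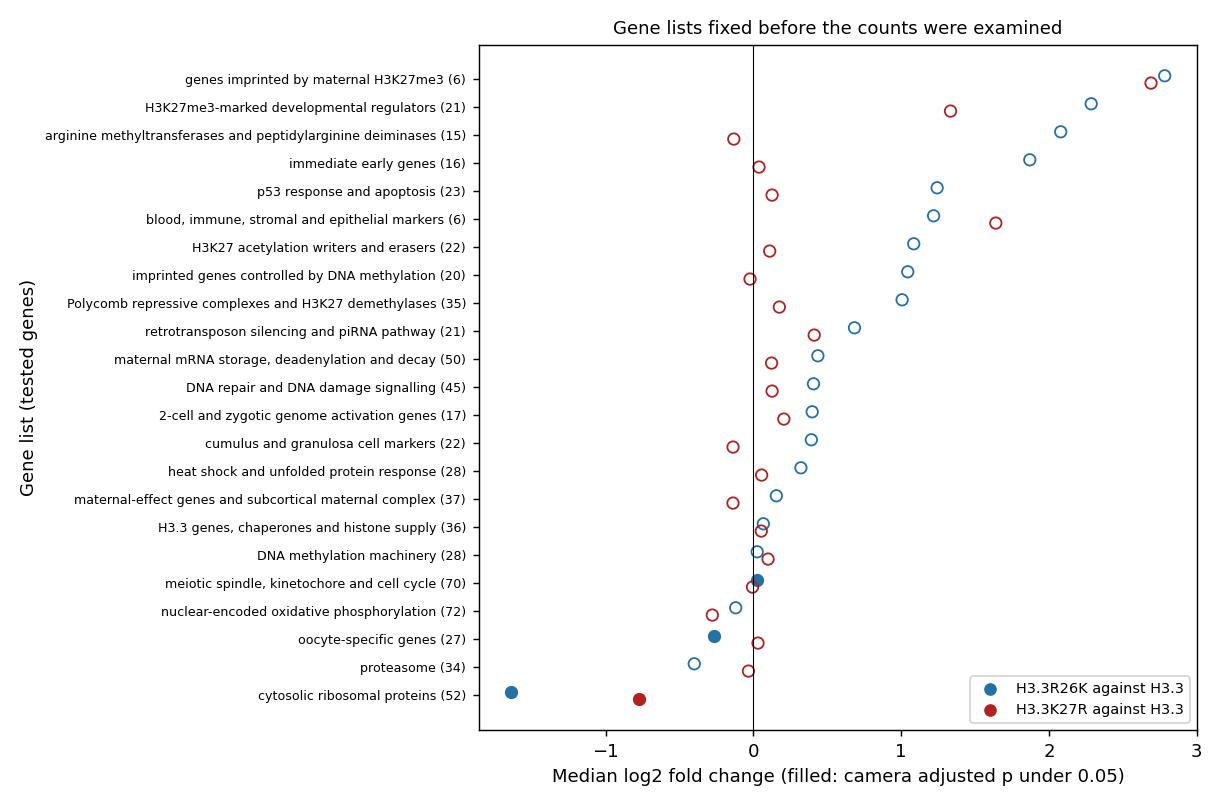
Median log2 fold change against H3.3 of each gene list with at least 5 tested genes (number in parentheses), for R26K and for K27R, with genes without counts in 1 group set at the limit that 3 counts per library give. Filled symbols passed camera with a preset correlation and none of them with an estimated correlation (adjusted p = 0.826 in R26K and 0.930 in K27R): ribosomal proteins at -1.64 in R26K and -0.78 in K27R (-0.0078 without H3.3 replicate 2), and the oocyte-specific and spindle lists in R26K, the last with a median that turns negative under other scalings.

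The second comparison asked the same of eggs with K27R, where no gene passed in either direction by edgeR (lowest adjusted p = 0.522). An unadjusted p under 0.05 was reached by 759 genes, where chance gives 533, with 645 higher and 114 lower in K27R. DESeq2 called 517 higher and 142 lower. The 10 abundant genes with the smallest p all had higher values in K27R, each with an edgeR adjusted p of 0.522. Stx6, Fam50a, Mad2l2, L3mbtl2 and Mettl15 had no count in H3.3. In K27R they were 120-fold, 197-fold, 187-fold, 303-fold and 241-fold above the floor of 3 counts per library. Such floors, and the counting intervals below, cover counting error only. Of genes at 10 to 20 CPM in the other libraries, 32.2% and 35.5% also had no count in H3.3 replicates 1 and 2, so a 0 there does not bound the level. Zfp212 was at 4.37 and 5.27 CPM in H3.3 and at 77.1 and 65.8 CPM in K27R (3.89 ± 0.59). Pdp1, a phosphatase of pyruvate dehydrogenase, was at 2.38 and 0.680 CPM in H3.3 and at 75.9 and 77.7 CPM in K27R (5.64 ± 0.88). Cxxc1 and Hmgxb3 had 1 and 2 counts in H3.3 and 621 and 835 in K27R, ratios of 676 (95% counting interval 121 to 26732) and 454 (125 to 3757). Exons of L3mbtl2, Mettl15 and Hmgxb3 overlap those of Chadl, Kif18a and Csf1r. On simulated counts with these means and depths, the edgeR test recovered 7.16% of genes changed 4-fold in K27R, 38.9% of those changed 16-fold and 59.7% of those changed 64-fold. Without R26K replicate 1 or R26K replicate 2, 5 and 3 genes were called higher and 0 lower, with 11879 and 11831 genes tested in place of 10667.

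Of the lists, only the cytosolic ribosomal proteins were called in K27R by camera, with 39 of 52 members below 0 and a median of -0.78 (adjusted p = 0.00045). No member passed by itself. The call was lost with an estimated correlation (adjusted p = 0.930), and without H3.3 replicate 2 the median was -0.0078 and the adjusted p 0.572. The other 22 lists had adjusted p from 0.463 to 0.999. Single members are given as values without a call. The spindle kinase Aurkb had no count in H3.3 and 17.6 and 17.3 CPM in K27R, and the p53 family member Trp63 none in H3.3 and 32.1 and 44.4 CPM in K27R. The chaperone Hspa5 was at 288 and 188 CPM in H3.3 and at 99.7 and 112 CPM in K27R. The histone chaperone Nasp was at 104 and 74.7 CPM in H3.3 and at 199 and 180.4 CPM in K27R. Adjusted over the list alone, L3mbtl2 passed in the Polycomb list (0.0177) and Trp63 in the p53 list (0.0334), both with an edgeR adjusted p of 0.522 over all genes. These were also the 2 lists with genes that differed in either direction by fry (adjusted p = 1.1e-04 and 0.0356). That test does not compare a list with other genes, and L3mbtl2 and Trp63 had no count in either H3.3 library.

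The third comparison set the libraries of both substitutions against each other. Higher in K27R than in R26K were Arid5b (5.92 ± 0.45), Paip1 (5.28 ± 0.33), Camk2g (4.41 ± 0.43), Klhl9 (4.30 ± 0.47) and the nucleoporin Nup98 (3.93 ± 0.41). Lower were Zar1 (-4.41 ± 0.28), Ptov1 (-4.32 ± 0.51), Sap30, of the Sin3 histone deacetylase complex (-3.92 ± 0.47), and Arrdc2 (-3.74 ± 0.31). In all, 18 genes were higher and 22 lower in K27R (edgeR adjusted p under 0.05). Of the maternal-effect list, Zfp57 was higher (1.96 ± 0.23) and Zar1 and Zbed3 (-3.04 ± 0.25) lower, and 34 of 37 did not pass. Phf1 (-3.41 ± 0.29) was the 1 called member of the Polycomb list and Asf1a (-3.48 ± 0.37) of the H3.3 and chaperone list. Adjusted over the list alone, 3 were higher and 3 lower in the maternal-effect list, 1 and 4 in the Polycomb list, and 1 and 2 in the H3.3 and chaperone list. The calls were lost without K27R replicate 1 or K27R replicate 2. All 40 genes kept their direction, and their median absolute log2 fold change was 3.25 and 3.37, against 3.27 with all libraries. These genes were picked from the same libraries, so the kept directions and folds do not show that the folds are stable. Without H3.3 replicate 1 or H3.3 replicate 2 the counts were 27 and 72 or 24 and 74, and without R26K replicate 1 or R26K replicate 2 they were 52 and 88 or 41 and 95. DESeq2 called 248 higher and 503 lower, a fit of only these 4 libraries 7 and 25, upper-quartile scaling 23 and 17, and the GC and length correction 13 and 7.

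Camera called 4 lists between K27R and R26K with a preset correlation, and none with an estimated correlation (adjusted p = 0.836 for the ribosomal proteins and 0.727 for the other lists). The cytosolic ribosomal proteins (41 of 52 above 0, median 0.93, adjusted p = 0.00047), the oocyte-specific genes (18 of 27 above 0, median 0.30, adjusted p = 0.0020) and the proteasome (22 of 34 above 0, median 0.31, adjusted p = 0.0454) stood higher in K27R. The arginine methyltransferases and deiminases stood lower (12 of 15 below 0, adjusted p = 0.0245), with a median of -1.20 when genes without counts in 1 group were set at their limit. Among them Jmjd6, whose exons overlap those of Mettl23, was at 11.2 and 8.64 CPM in K27R and at 115 and 85.0 CPM in R26K (edgeR adjusted p = 0.224). The 19 lists not called had adjusted p from 0.179 to 0.988. Without K27R replicate 1 the ribosomal, proteasome and arginine lists did not pass (0.114 for each), and the ribosomal and proteasome medians were -0.42 and -0.17. Without K27R replicate 2 the oocyte and proteasome lists did not pass (0.103 for both), without R26K replicate 1 the arginine list (0.102), and without R26K replicate 2 the arginine and proteasome lists (0.0505 for both).

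The effects of both substitutions against H3.3 correlated across genes with r = 0.748 over 10667 genes, which are not independent replicates. Both effects share the H3.3 libraries. Unchanged groups were simulated, H3.3 included, with the same mean and dispersion of a gene in every library. They gave r of 0.492 on average (0.471 to 0.512 in 50 simulations), where ratios of pooled counts in the data gave 0.745. The covariance was 11.9 in the data and 3.73 in the simulations, a difference of 8.19. The simulated groups had equal spread, while the median absolute log2 difference between replicates was 1.02 in H3.3, 0.855 in K27R and 0.332 in R26K. A more variable shared control raises r by itself, so 0.492 is not a safe reference and the excess is not read as a shared effect. The controls were only 2 libraries and were not split, so part or all of the excess may come from them. Of the tested genes, 2210 had no count in either H3.3 library, and over the 8457 genes with an H3.3 count r was 0.558. Over the 2854 genes with a mean of at least 50 CPM, a bound chosen after the data were seen, r was 0.521. Without K27R replicate 1, r was 0.497. Unchanged groups were not simulated for these subsets, so the simulated 0.492 is no reference for them.

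**Figure D4:**
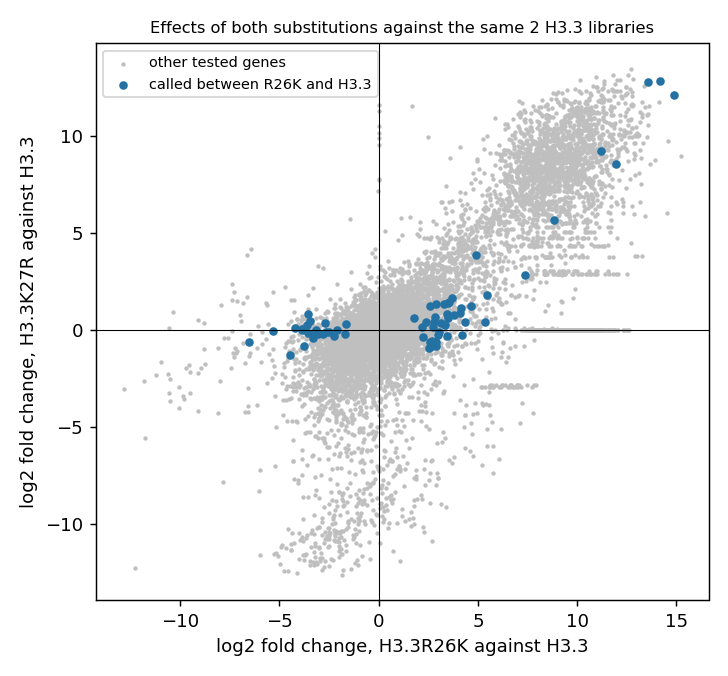
Log2 fold change against H3.3 of each tested gene in R26K (horizontal axis) and in K27R (vertical axis), with the 66 genes called between R26K and H3.3 in blue. The cloud at the upper right holds genes without counts in the H3.3 libraries, whose fitted values depend on the prior count; r is 0.748 over all tested genes and 0.558 over those with an H3.3 count.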

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

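The tests by thinning, by the GC and length correction and by library totals were chosen after the calls between R26K and H3.3 were seen. For thinning and the correction, the ratios that would argue against a cause (above 0.9 and above 0.75) were set before the ratios were computed. The bootstrap intervals over genes were added only after the second ratio, 0.753, had been seen: taken alone it lies just above 0.75 and would argue against the trend, and it is read as open here because its interval reaches below that bound.

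A direct test found that 18 genes were higher and 22 lower in the K27R libraries than in the R26K libraries, Paip1, Arid5b and Zar1 among them. All 18 higher in K27R were also called lower in R26K than in H3.3, and 18 of the 22 also higher in R26K than in H3.3. This comparison thus largely repeats the separation of the R26K libraries. A separate batch of these, described below, cannot be told apart here either. The GC and length correction kept 17 of these 40 calls and brought their median absolute log2 fold change from 3.27 to 2.63. The calls were lost without K27R replicate 1 or without K27R replicate 2. All 40 kept their direction and the median absolute log2 fold change was 3.25 and 3.37, against 3.27 with all libraries. Since the genes were picked from these same libraries, that does not show stable folds.

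Both R26K libraries stood apart from the other 4 in the 66 genes called between R26K and H3.3. After every library was thinned to 10803477 counts, the median absolute log2 fold change of the 66 genes was 0.997 of its value (95% bootstrap interval 0.985 to 1.02). All 66 were still called, so the calls did not need the extra reads. Thinning keeps the expected share of each gene in a library, and all 66 genes averaged at least 10 CPM. The ratio, though above 0.9, was thus bound to stay near 1 and does not decide on deeper sequencing as a cause of the folds. A trend with GC content and length is left open. The genes called higher had a median GC content of 54.7% and those called lower 44.9%. The correction brought the median from 3.39 to 2.55, a ratio of 0.753 (0.676 to 0.940). With these smaller folds and a median SE of 0.380 in place of 0.354, 17 of the 66 were still called. Both bootstrap intervals treat genes as independent although they share the same libraries, so they do not measure the spread between libraries. A separate preparation or sequencing batch of the R26K libraries cannot be told apart from the substitution, because no library of another group came near their depth (the smaller R26K total was 2.65 times the highest other total). The fluorescent tag, eCFP in R26K and eGFP in H3.3, cannot be told apart from the substitution either. An effect of the R26K histone on egg transcripts stays open and was not tested apart from these.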

How the results depend on the processing

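Among these settings the 50 CPM filter, thinning and the GC and length correction were chosen after the data were seen. The cause was not tested for any change, beyond that the filters change which genes are tested, and that left-out libraries leave fewer samples and, through the expression filter, more tested genes (11831 to 12440 in place of 10667). Counts are given as higher and lower. DESeq2 gave 517 and 142 for K27R against H3.3, 1207 and 421 for R26K against H3.3, and 248 and 503 for K27R against R26K; on simulated counts it made from 226 to 300.6 false calls per simulation. For R26K against H3.3 and then K27R against R26K, no filter gave 178 and 63, and 56 and 100; the 10 CPM filter 115 and 42, and 37 and 58; the 50 CPM filter 227 and 128, and 103 and 175; a fit of only the groups compared 0 and 0, and 7 and 25; the GC and length correction 6 and 17, and 13 and 7. With the replicate number as a block the counts were 0 and 0 for K27R against H3.3, 195 and 65 for R26K against H3.3, and 61 and 134 for K27R against R26K. Deviations of same-numbered libraries correlated at 0.013, -0.010 and 0.0037, so no shared source of these libraries was seen. The labels do not say whether the number marks one, and these values do not exclude it. Under the block the proteasome was also called for R26K against H3.3 (adjusted p = 0.0298), and no other list call changed. With each library left out, a lone library being assumed to vary like the others, the ranges were 0 to 5 and 0 to 0 for K27R against H3.3, 1 to 147 and 0 to 56 for R26K against H3.3, and 0 to 52 and 0 to 95 for K27R against R26K. The r of both effects ranged from 0.497 to 0.732. The lists called went from 1, 3 and 4 to 0, 0 and 0 with an estimated correlation and to 0, 0 and 0 with fry. Relative log and upper-quartile scaling, the robust spread and thinning kept every count within 1.5 times. The median log2 fold change of all genes in R26K was 0.66, 0.57 with relative log and 0.47 with upper-quartile scaling, while the ribosomal list lay -2.30 from it under each. Over the 2854 genes with a mean of at least 50 CPM the median was 0.02.

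The 66 genes called between R26K and H3.3 kept their direction under every setting that tested them, 2 of them being left untested by the 50 CPM filter. For left-out libraries this was all but fixed in advance, since both R26K libraries lay outside the other 4 in each gene. For the named genes, 608 values stayed on their side of the threshold, 127 lost the call and 54 gained it between R26K and H3.3. The numbers were 498, 44 and 40 for K27R against R26K, and 505, 0 and 29 for K27R against H3.3. Signs changed only for 2 uncalled genes in K27R: H3f3b to -0.046 with DESeq2 and with relative log scaling, -0.016 with the 50 CPM filter and -0.075 with the correction (-0.27 to 0.23 over left-out libraries), and H3f3a (-0.50 to 0.20). Rps27a in K27R ranged from 0, without K27R replicate 1, to 8.76, a fitted value without H3.3 counts. By depth, 3 counts stand for 0.285 CPM in K27R replicate 2, the smallest library, 0.230 and 0.255 CPM in H3.3, and 0.0815 and 0.0907 CPM in R26K.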

Other observations

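The tests on detected genes in this part were chosen after their result was seen, and so was the comparison of all searched genes with and without the polyadenylation element. The tests on the element in called genes and on pseudogenes were not among those fixed beforehand. Both address patterns already seen in the data, though their criteria were set before the test values were computed. Several lists held members that passed only when adjusted over the list alone in R26K against H3.3. Apart from Cnot11, Oosp2, Sdf2l1 and Dusp1, they are named here after their values were seen. In the list of maternal mRNA storage and decay, Cnot8, Cnot11, Edc4, Ybx3 and Eif4enif1 were higher, by 1.64 to 3.13 on the log2 scale, and Pan3 (-2.13), Lsm14b (-2.62) and Pum2 (-3.30) lower. None of the 50 passed over all genes. In the oocyte-specific list, Oosp2 (-1.38), Oosp3 (-0.999), Oog3 (-0.95) and Oog4 (-1.39) were lower and Lhx8 higher (75.3 and 73.7 CPM against 0 and 0.595 CPM). The value of Oosp2 was -0.22 after the GC and length correction. In the heat shock and unfolded protein list, Hsp90aa1 (-1.18) and Canx (-1.65) were lower and Sdf2l1 (3.45) higher. The immediate early gene Dusp1, whose exons overlap those of Ergic1, was higher by 2.42, and by 1.07 after the correction. Actb, also chosen after it was seen, was at 89.0 and 207 CPM in H3.3, 190.0 and 63.0 in K27R, and 14.3 and 19.9 in R26K (edgeR adjusted p = 0.155 for R26K against H3.3).

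One hypothesis is that the R26K libraries differ in poly(A) tails, since the cDNA was primed on them and stored egg transcripts gain or lose tails during maturation. Genes called higher in R26K carried a cytoplasmic polyadenylation element near the end of the 3' UTR in 17 of 42 searched cases, against 1383 of 5777 other genes with a mean of at least 10 CPM. The odds ratio was 2.16 (95% interval 1.09 to 4.18, Fisher's exact test, two-sided p = 0.0176). This was 1 of 4 explanations tried for the same genes, and the p is not adjusted for that. Of the genes called lower, 6 of 23 carried the element (odds ratio 1.12, 0.361 to 2.99). Over the searched genes, called or not, the median log2 fold change was 0.14 in the 1406 with the element and 0.077 in the 4436 without. The element may mark some of the called genes, but 40.5% of those searched carried it; a difference in maturation or in egg handling was not tested.

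The libraries differ in the number of genes detected, and read depth is argued against as the whole cause: after thinning the highest number was still 1.61 times the lowest. Loss of transcripts before amplification stays open. In each of the 3 libraries with the fewest genes at least 32.2% of the genes at 10 to 20 CPM elsewhere had no count, but these libraries were picked by their number of genes, and separate samples differ by more than read sampling, so this share does not decide it. A share of at least 5% was first set to count for such loss, and that reading was dropped after the share was seen. The input in eggs, RNA quality and differences in expression stay open as well, and no biological explanation was tested.

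Of the 79 ribosomal protein genes, 36 were under 1 CPM on average, while the highest was at 78.3 CPM. Reads shared with processed pseudogenes are a candidate explanation: across the 79 genes the mean CPM fell with the number of similar pseudogenes (at least 90% identity over 150 bases) (Spearman rho -0.475, permutation p = 1e-05, the smallest that 100000 permutations can give). Genes are not independent replicates. The 11 genes with 2 or fewer copies had a median of 18.7 CPM and the other 68 a median of 0.875 CPM. Copies do not account for the lower values in R26K, since the 10 tested genes with 2 or fewer copies were all below 0 in R26K against H3.3 (median -1.84). How reads with several positions were counted is not given in the sources used here.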
